A study of Bos taurus with 6 samples.

How the data were processed

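Total RNA from 6 agarose cultures of bovine bone marrow MSCs was measured on Affymetrix bovine arrays, 1 array per condition. Per the labels' protocols, RNA was taken up in a pair of successive TRIZOL-chloroform extractions, amplified linearly with the NuGEN ribo-SPIA method, fragmented and labelled with biotin. The deposited values are the authors' linear signal intensity per probe set, made with MAS5 per the submitters' processing notes, with the version not given in the sources used here. The mean signal after trimming 2% of probe sets at each end was 150 on every array, as a global scaling by the authors would leave it, and the arrays' quantiles differed, so no step equalising whole distributions was apparent.

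The table held 24128 probe sets, of which 112 controls were left out of the comparisons, leaving 24016. Of these 13292 had 1 gene name, 86 had several and 10638 were unnamed here. Names came from the platform annotation and were checked through Entrez identifiers, of which 13263 were found and none gave another symbol. No gene was named from a probe set with several genes. For 1 value per gene, the probe set with the highest mean log2 signal over the 6 arrays was taken, which gave 9155 genes. SOX9, a gene chosen in advance to be named, had no named probe set here.

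The authors' scaling was kept. The floor was the 40th percentile of all values, a signal of 15.1. Values under it were set to it and log2 values were taken. A probe set entered a comparison if it was above the floor on at least 1 of the 2 arrays, and counted as higher or lower at a log2 difference of at least 1. A gene with 1 side under the floor is given as at least N-fold, and its log2 difference is likewise a bound. With 1 array on each side no p-value was computed for these comparisons. Over days 21 and 42 TGF-beta3 had 2 arrays on each side, 1 of each per day, so it was also tested on these 4 arrays with limma 3.58.1 in R 4.3.3, using a term for day, itself not tested, moderated variances with a trend on signal, and Benjamini-Hochberg adjusted p under 0.05, on 14839 probe sets above the floor on at least 2 arrays. The fit had 1 residual degree of freedom per probe set and a prior worth 49.8, so the p-values rest mainly on the pooled spread. "Rose" and "fell" refer to this test, and "higher" and "lower" to the size of a difference. Whether the cultures of the 2 days came from separate donors is not given in the sources used here.

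There were 23 gene lists, fixed with the tests, the named-gene rule and most alternatives before the data were examined. For each list the median log2 difference was set against 10000 random lists of the same size, drawn with replacement from the same deciles of signal. The percentile describes these arrays, and genes are not replicates. The genes named were the 10 highest and 10 lowest above the floor on both arrays (5 for comparisons of days), the 2 highest and 2 lowest members of each list past the size rule, a set of 10 cartilage and matrix genes whatever their values, and the 10 largest mean differences per direction among those past the limma test. A gene named in 1 comparison is also quoted in others. Symbols beginning with LOC, MGC or KIAA or holding only an open reading frame number were left out as placeholders, a form settled after the values were seen. Other members of a list that passed the limma test, and the metallothioneins MT1A and MT2A, were named after their values were seen.

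The limma step was tested on simulated data for the TGF-beta3 comparison with 14839 probe sets, 200 of them changed. It recovered 9% of log2 changes of 1 and 56% of changes of 2, and called 1 unchanged probe set, so small changes were mostly missed there. On the real arrays 1954 probe sets were called, which eases the adjusted p threshold, and the simulated noise held no shift of a whole array. The 9% and 56% are thus not the power of the real test. Nor does the 1 tell how many real calls are false. The size rule was tested on 24016 simulated values of the loading pair, where 100% of 200 changes of log2 2, placed in bright probe sets with little added noise, were found and 0 unchanged ones were counted, and 6.5% of 200 unchanged lists of 15 genes fell outside the central 95% of random lists. The added noise was far under the size rule, so the 0 does not tell how many counts on the real arrays are noise. Alternatives were quantile normalization, median centring, floors at the 25th and 60th percentiles, the floor value added in place of a floor, thresholds of 1.5-fold and 3-fold, genes in place of probe sets, the median of a gene's probe sets, other variance priors, no day term, the loaded array added and each array left out. After the data were seen, a floor at a signal of 100 and the loaded array in place of the unloaded one were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The constructs' mechanical and biochemical measurements were not analysed here.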

Results

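Gene expression was profiled on 6 bovine Affymetrix arrays, 1 for each of 6 conditions of bone marrow mesenchymal stem cells (MSCs) held in agarose hydrogel. The cells were kept in a defined medium without transforming growth factor beta 3 (TGF-beta3) for 3, 21 or 42 days, or with it for 21 or 42 days. A further construct with TGF-beta3 grew unloaded for 21 days and was then compressed cyclically for 21 days, up to day 42. TGF-beta3 is a growth factor used to drive MSCs towards cartilage cells (chondrogenesis), and agarose transmits compression to cells and to the matrix they lay down. The comparisons asked how TGF-beta3, time in culture and compression altered the transcripts of these cells. With 1 array per condition there were no replicates, and the number of arrays limits the precision of every value below.

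The arrays had median signals between 22.3 and 34.9, and between 54.9% and 65.3% of their probe sets lay above the floor of 15.1. Hybridisation spikes are foreign transcripts added in fixed amounts to each hybridisation. Their median signal was between 2617 and 3727 on the 3 arrays without TGF-beta3 and the day 21 array with it, but 7304 on the unloaded and 5822 on the loaded day 42 array with TGF-beta3. Relative to day 3, the spikes and the 27 ribosomal protein genes shifted together, by log2 1.05 and 1.04 on the unloaded and by 0.65 and 0.59 on the loaded array. These shifts stand beside every day 42 comparison with TGF-beta3. The 3 prime to 5 prime signal ratio of control probe sets, a planned technical reference, also varied between arrays. It lay between 1.51 and 2.27 for GAPDH, 4.86 and 7.52 for cyclophilin and 5.08 and 9.10 for eIF4E. From the unloaded to the loaded array cyclophilin went from 4.95 to 7.52 and eIF4E from 7.41 to 8.05, but GAPDH from 2.15 to 1.80. Whether this bears on the comparisons was not tested.

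**Figure D1:**
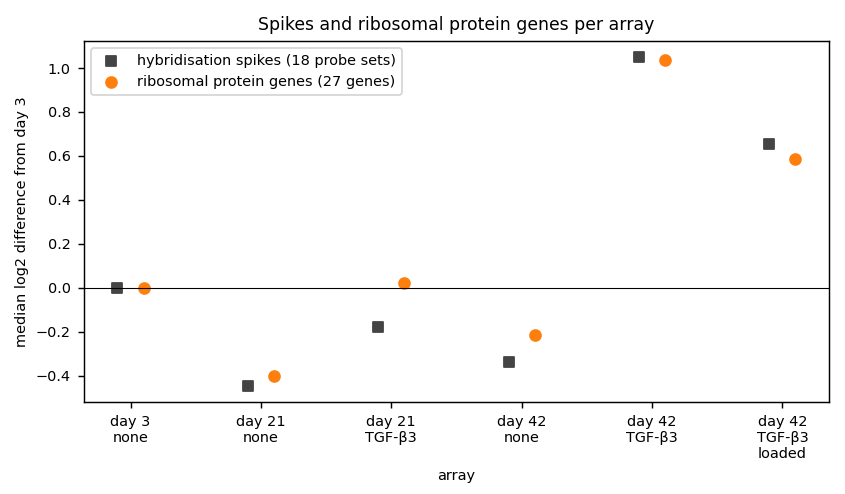
Median log2 difference from the day 3 array (y axis) of the 18 hybridisation spike probe sets (squares) and of the 27 ribosomal protein genes (circles) on each array (x axis). Both lie between -0.45 and 0.02 on the arrays of day 21 and of day 42 without TGF-beta3, and between 0.59 and 1.05 on the 2 day 42 arrays with TGF-beta3.

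TGF-beta3 went with a cartilage matrix programme. Over days 21 and 42, 9 of the 11 cartilage matrix genes tested rose and none fell. Aggrecan (ACAN), the large proteoglycan that holds water in cartilage, was 4.23-fold higher at day 21 and 5.67-fold higher at day 42, and type II collagen (COL2A1), the main fibril collagen of cartilage, 3.82-fold and 6.49-fold, on the brightest of its 4 probe sets. With values under the floor set to it, the other 2 ACAN probe sets were higher by log2 2.33 and 2.35 at day 21. At day 42 they were higher by only 1.22 and 1.82. The other 3 COL2A1 probe sets were under the floor without TGF-beta3 at day 21 and were higher by at least log2 2.86 to 6.09 there, and by log2 2.55 (a bound) to 6.13 at day 42. Cartilage oligomeric matrix protein (COMP), which binds collagen fibrils, was 24.0-fold and 22.1-fold higher. Chondroadherin (CHAD), a cartilage protein that binds cells and collagen, lay under the floor without TGF-beta3 and was at least 106-fold higher at day 21 and at least 120.1-fold higher at day 42. Its mean log2 difference with its standard error was 6.82 ± 0.50 (adjusted p = 8.8e-16 by limma), and that of COMP was 4.52 ± 0.34 (adjusted p = 2.1e-15 by limma). The CHAD mean is a bound set by the floor. It was 7.36 with the floor at the 25th percentile and 4.09 with the floor at a signal of 100, while that of COMP stayed at 4.52. The link protein HAPLN1, which ties aggrecan to hyaluronan, was already bright without TGF-beta3 (signal 3029 at day 21). It rose by a mean log2 of 1.41 ± 0.39 (adjusted p = 0.00988 by limma). The call was lost without the variance trend (adjusted p = 0.133 by limma) or without the day term (0.129). HAPLN1 was higher by log2 0.85 at day 21 and 1.96 at day 42, on array pairs whose spikes differed by 0.27 and 1.39. Under quantile normalization its mean was 0.98. COL9A1, COL11A1, COL11A2 and COL27A1 were the other members that rose. The chondrogenic transcription factor list had 1 measured member, PITX1, at 3.33-fold higher at day 21 and at least 2.33-fold at day 42, which did not pass the test (adjusted p = 0.101 by limma).

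**Figure D2:**
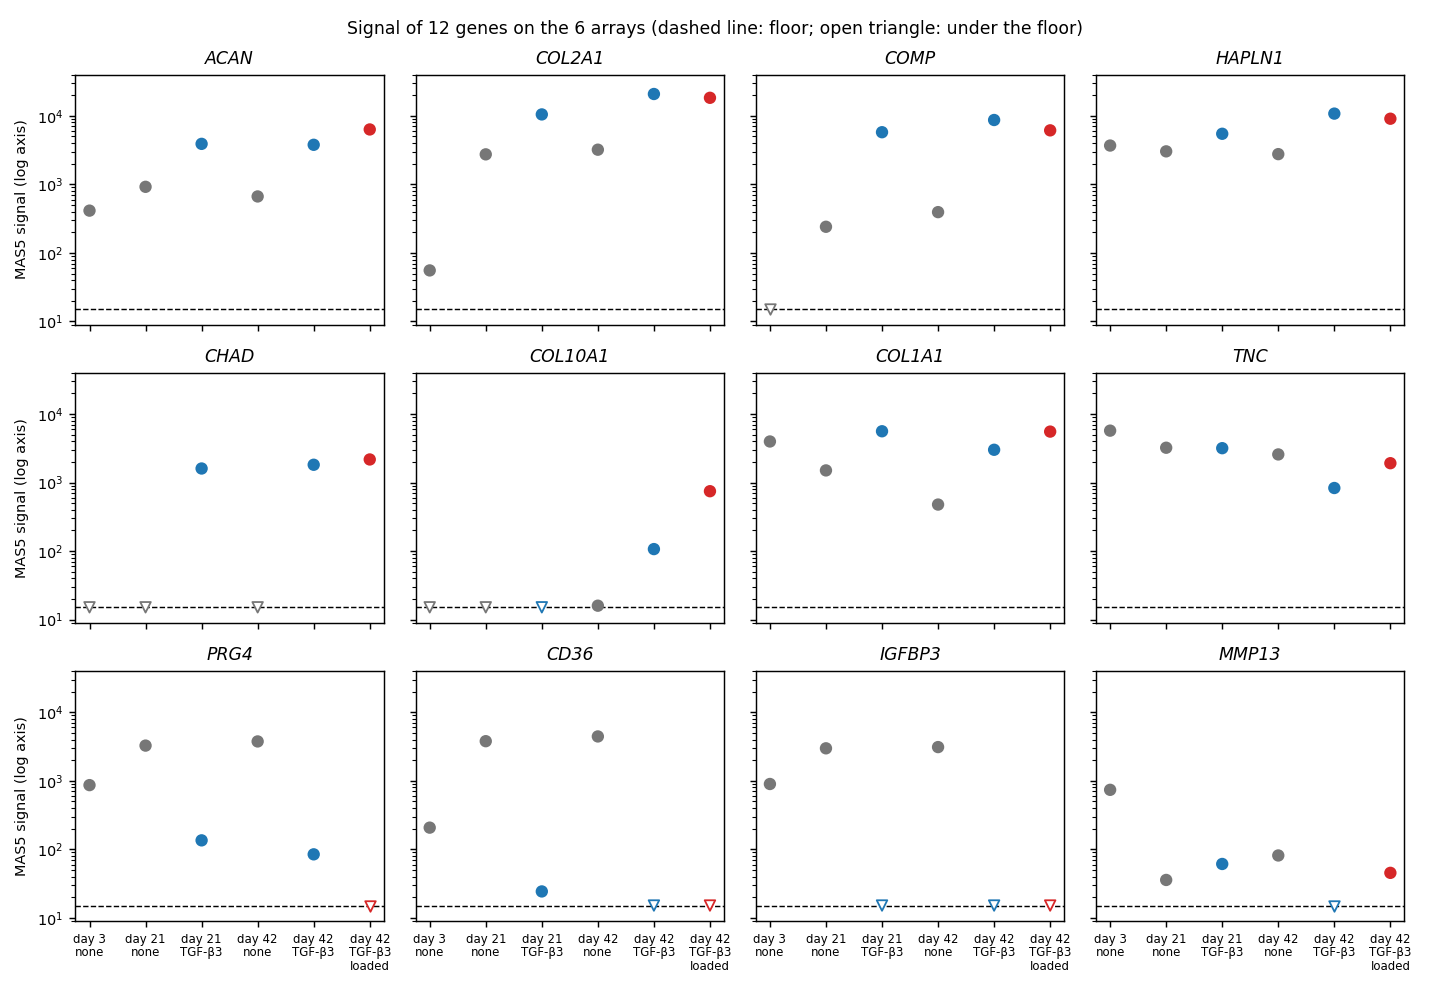
MAS5 signal (y axis, log scale) of 12 genes on the 6 arrays (x axis), 1 point per array. Grey marks arrays without TGF-beta3, blue those with it and red the loaded array, the dashed line is the floor, and open triangles mark values under it. COMP signal was between 5762 and 8684 on the 3 arrays with TGF-beta3 and at most 393 without it, while PRG4 was at most 135 with it and at least 865 without.

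Across all 14839 probe sets tested over both days, 866 rose and 1088 fell with TGF-beta3 (limma with a term for day, Benjamini-Hochberg adjusted p under 0.05), a split of 488 and 1008 under median centring. With 1 probe set per gene, 486 of 6835 genes rose and 526 fell, the background for the counts of each list, not matched on signal. With the floor at a signal of 100, 801 of 7995 probe sets rose and 960 fell. That is a larger share than over all 14839, so the background may be low for lists of bright genes. By size alone, 2051 of 15466 probe sets were at least 2-fold higher and 2429 lower at day 21, and 4127 of 16874 were higher and 2734 lower at day 42. Median centring of the arrays turned the day 42 split to 2472 higher and 4820 lower, as it moved the median difference of all probe sets from log2 0.21 to -0.29. The 2 days share no array. Of 6748 genes compared on both, 549 were at least 2-fold higher on both days, where independent lists would share 227, 551 were lower on both (expected 167) and 71 went opposite ways (expected 395). The p-values set the mean difference of the 2 days against a spread pooled over probe sets of like brightness, not that of independent cultures. A probe set's own disagreement between the days weighs little in them. Of the 1954 called, 1952 had the same sign on both days. Choosing probe sets by a large mean difference makes this likely, so it is no separate evidence that a difference repeats. The sizes could differ between the days. CHPF rose with log2 differences of 0.57 and 3.67 at days 21 and 42, and RRM2 with bounds of 4.60 and 0.72. The count of 1954 was 1030 without a variance trend, 570 without the day term and between 340 and 3773 with 1 array left out and no day term, fits in which an arm has 1 array. Of the cartilage matrix genes 6 rose without the day term and between 3 and 9 in the fits that left an array out.

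Other matrix genes rose with TGF-beta3 as well. In the fibrous matrix list, 9 of 17 genes rose and 1, fibrillin 1 (FBN1), fell. Elastin (ELN) was at least 27.2-fold and at least 49.6-fold higher at days 21 and 42, dermatopontin (DPT) 22.5-fold and 22.9-fold, periostin (POSTN) 22.7-fold and 6.92-fold, and type I collagen (COL1A1), the collagen of bone and tendon, 3.73-fold and 6.30-fold. Tenascin C (TNC) did not pass the test, with log2 differences of -0.02 and -1.63 and a second TNC probe set at least 0.44 higher at day 42. Among genes that modify and crosslink collagen, 11 of 20 rose and 1 fell (PCOLCE2). They included the prolyl hydroxylase P4HA1 (5.88-fold and 4.10-fold higher), the collagen chaperone FKBP10 (4.61-fold and 10.2-fold), and the crosslinking enzymes LOX (2.57-fold and 8.05-fold) and LOXL4 (8.93-fold and 2.58-fold). The glycosaminoglycan synthesis list had 3 of 14 members rise, among them CHST11, which sulphates chondroitin (at least 8.02-fold and at least 4.96-fold higher), and CHPF, which lengthens its chains (1.49-fold and 12.7-fold). Without the day term 4 fibrous matrix, 6 collagen processing and 1 glycosaminoglycan synthesis genes rose, and without the variance trend 6, 5 and 1. With 1 array left out and no day term they were 4 to 7, 4 to 14 and 0 to 5.

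The small leucine-rich proteoglycans and lubricin moved apart. Biglycan (BGN) was 4.08-fold and 6.78-fold higher at days 21 and 42, asporin (ASPN) was higher by log2 3.00 and at least 2.67, and 4 of the 10 members rose. Lubricin (PRG4), the lubricant of the joint surface, fell with a mean log2 difference of -5.03 ± 0.35 (adjusted p = 2.6e-16 by limma), from a signal of 3263 to 135 at day 21 and from 3752 to 84.6 at day 42, and clusterin (CLU) fell too. Without the day term 2 members rose and 1 fell, and 1 to 6 rose with 1 array also left out. In the hypertrophy and mineralisation list, 2 of 11 members rose (1 without the day term, 1 to 7 with 1 array also left out and 5 with the loaded array in place of the unloaded one). At day 42 alone 8 of 15 were at least 2-fold higher (median log2 1.31, percentile 99.9 of random lists), on the array pair whose spikes differed by 1.39. The angiogenic factor VEGFA was 17.3-fold and 14.9-fold higher and ENPP1, which makes pyrophosphate, was the other. Type X collagen (COL10A1), the collagen of hypertrophic cartilage, was under the floor on both day 21 arrays and was 6.70-fold higher with TGF-beta3 at day 42, at a signal of 107 against 16.0. The collagenase MMP13 was 1.71-fold higher at day 21 and at least 5.38-fold lower at day 42 and did not pass the test (adjusted p = 0.522 by limma).

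Genes of growth factor pathways were altered in both directions. In the TGF-beta and BMP list, 6 of 18 members rose and 1 fell. The matrix protein TGFBI, named for its induction by TGF-beta, was 18.1-fold and 17.5-fold higher, the activin subunit INHBA 10.6-fold and 11.5-fold higher, and the ligand TGFB2 fell, from a signal of 1263 to 250.3 at day 21 and from 701 to 175 at day 42. Among Wnt, hedgehog and growth factor genes, 3 of 16 rose and 5 fell. IGFBP3 and IGFBP5, which both bind insulin-like growth factors, went opposite ways: IGFBP3 was at least 197-fold and at least 205-fold lower, and IGFBP5 22.8-fold and at least 31.4-fold higher. The Wnt-binding SFRP4 was 17.5-fold and at least 139-fold lower, and the Wnt inhibitor DKK1 at least 13.2-fold and at least 4.03-fold higher, with a second DKK1 probe set at least log2 1.18 and 0.19 higher. Without the day term 3 TGF-beta and BMP genes rose and 1 fell, and 1 Wnt and growth factor gene rose and 3 fell. With 1 array also left out, 2 to 8 of the former rose, and 1 to 4 of the latter rose and 2 to 5 fell.

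Some contractile, glycolytic and cell cycle genes rose with TGF-beta3. In the smooth muscle and pericyte list 4 of 12 rose and 1, myosin light chain kinase (MYLK), fell. The actin-binding proteins transgelin (TAGLN) and calponin (CNN1) were 10.3-fold and at least 19.2-fold higher at day 21 and 6.52-fold and 2.79-fold higher at day 42. Of 20 adhesion and cytoskeleton genes, ACTN4 rose, VCL and CAV1 fell, and 17 did not pass the test. None of these 20 passed without the day term, without the variance trend or with either array without TGF-beta3 and the day term left out, and 3 rose and none fell without the day 42 array with TGF-beta3 and the day term. In the hypoxia and glycolysis list 7 of 16 rose, with BNIP3, a mitochondrial protein induced by low oxygen, 3.38-fold and 8.38-fold higher, while the glycolytic regulator PFKFB3 was 12.7-fold and 2.82-fold lower and fell. Of 20 cell cycle genes 7 rose and MCM7 fell, and at day 21 alone 17 of 22 were at least 2-fold higher (median log2 1.52), but 8 of 20 at day 42, where the list lay inside the central 95% of random lists (percentile 76.2). UBE2C, which works in mitotic exit, was at least 42.3-fold higher at day 21 and at least 11.4-fold at day 42, and RRM2, which makes DNA precursors, at least 24.3-fold at day 21 but at least 1.65-fold at day 42. Without the day term 1 cell cycle gene, 1 glycolysis gene and no smooth muscle gene rose, and with 1 array also left out 1 to 4, 2 to 11 and 1 to 4.

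Fat cell genes were among those that fell most. Of 14 adipocyte genes tested, 8 fell and none rose. The fatty acid transporter CD36 had a mean log2 difference of -7.74 ± 0.41 (adjusted p = 9.8e-21 by limma) and a signal of 3784 without TGF-beta3 at day 21 against 24.3 with it. The CD36 mean is a bound, since the gene was under the floor at day 42 with TGF-beta3. It was -8.48 with the floor at the 25th percentile and -5.36 with the floor at a signal of 100. PPARG, the transcription factor that drives fat cell formation, was 37.7-fold and 46.8-fold lower at days 21 and 42, and FABP4, ADIPOQ, LPL, FABP5, ACSL1 and LPIN1 also fell. Without the day term 6 fell, and with 1 array also left out 5 to 10, the lowest without the day 21 array without TGF-beta3, and 2 rose without the day 21 array with it. Lipid genes outside the list were among the 10 with the largest falls, namely DGAT2, which makes triglyceride (at least 133-fold and at least 133-fold lower), the lipogenic THRSP, the glycerol channel AQP7, ACSM1 and the pyruvate dehydrogenase kinase PDK4 (at least 84.5-fold and 107-fold lower).

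More inflammatory, blood cell and stromal genes fell than rose. Of 17 inflammation genes 6 fell and 2 rose. The pentraxin PTX3 had log2 differences of -5.64 and -6.04 and the chemokine CXCL5 was at least 13.0-fold and at least 21.9-fold lower, whereas the monocyte chemokine CCL2 was 45.0-fold and 7.31-fold higher and the hyaluronan-binding TNFAIP6 6.36-fold and 5.62-fold higher. The macrophage and blood cell markers AIF1, CD53 and CD68 fell and none of the 9 tested rose; AIF1 was at least 8.09-fold and at least 9.78-fold lower. S100A12, GPNMB and SLC11A1, genes known from macrophages and other myeloid cells, were also among the largest falls, with S100A12 89.7-fold and 306-fold lower. Of 13 marrow stromal cell genes 5 fell and 3 rose, with the chemokine CXCL12 at least 20.9-fold and at least 16.9-fold lower. Among proteases and inhibitors 3 of 19 rose and 4 fell. The urokinase PLAU was 17.1-fold and 6.70-fold higher and its receptor PLAUR 23.3-fold and 9.55-fold higher, and the lysosomal cathepsin B (CTSB) 4.01-fold and 3.17-fold lower, with another, dim CTSB probe set at least log2 0.16 higher at day 21. Without the day term 3 inflammation, 2 macrophage, 3 stromal and 1 protease gene fell. With either array without TGF-beta3 also left out, no macrophage, 1 stromal and 2 inflammation genes fell.

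The remaining lists were those of endothelial, immediate early, chaperone, interferon and ribosomal protein genes. ERG rose among 2 endothelial genes tested, and no endothelial gene without the day term. In the immediate early list 5 of 19 rose and 2 fell, with the cyclooxygenase PTGS2 at least 11.6-fold and at least 53.0-fold higher and the phosphatase DUSP1 5.75-fold and 6.03-fold lower. In that list 3 rose and 1 fell without the variance trend, and with 1 array and the day term left out 3 to 7 rose and 1 to 3 fell. The chaperone list had 2 rise and 2 fall of 18, with the heat shock proteins HSPA1A and HSPB1 falling, and 1 rise and no fall without the day term. No interferon gene of 4 tested passed, although at day 42 alone ISG15 was at least 20.9-fold and MX1 at least 8.03-fold lower with TGF-beta3. Both bounds rest on the day 42 array without TGF-beta3 (signals 317 and 122), which also serves the comparison of days 21 and 42 without it. Of 27 ribosomal protein genes, RPL13 passed, and 25 rose without the day 21 array with TGF-beta3 and the day term. At day 42 alone 24 of the 27 were at least 2-fold higher, with a median log2 difference of 1.28, on an array pair whose spikes differed by 1.39 in the same direction. Adjusted over the list alone, the counts that rose and fell were 10 and 0 for cartilage matrix and 1 and 0 for chondrogenic transcription factors. The latter list had 1 gene tested, PITX1, so its p-value was in effect unadjusted. The counts were 10 and 2 for fibrous matrix, 5 and 0 for glycosaminoglycan synthesis and 13 and 1 for collagen processing. They were 10 and 3 for the TGF-beta and BMP pathway, 4 and 4 for proteases, 1 and 10 for adipocyte, 3 and 7 for stromal, 0 and 4 for macrophage and 2 and 7 for inflammation genes. For immediate early genes they were 7 and 2, for cell cycle 10 and 1, for hypoxia 11 and 1 and for ribosomal protein genes 0 and 0, and the other lists kept their counts adjusted over the list alone.

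The 10 genes with the largest rise over both days also included several outside the lists. The prostaglandin synthase PTGES was 24.4-fold higher at day 21 and at least 186-fold at day 42, and the retinoic acid carrier CRABP2 at least 50.4-fold and at least 51.5-fold. CLEC3A, a lectin known from cartilage, was at least 95.9-fold and at least 122-fold higher, LRRC1 at least 46.8-fold and at least 79.7-fold, the mitochondrial NDUFA4L2 45.0-fold and at least 45.9-fold, the matricellular SMOC2 33.5-fold and at least 51.1-fold, and ANGPTL2 41.6-fold and at least 39.7-fold. The class II histocompatibility gene BOLA-DQB1 was 64.9-fold and 115-fold higher on a probe set that can match related genes, while its other probe sets measured at day 42 were higher by at least log2 0.69 to 1.92.

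**Figure D3:**
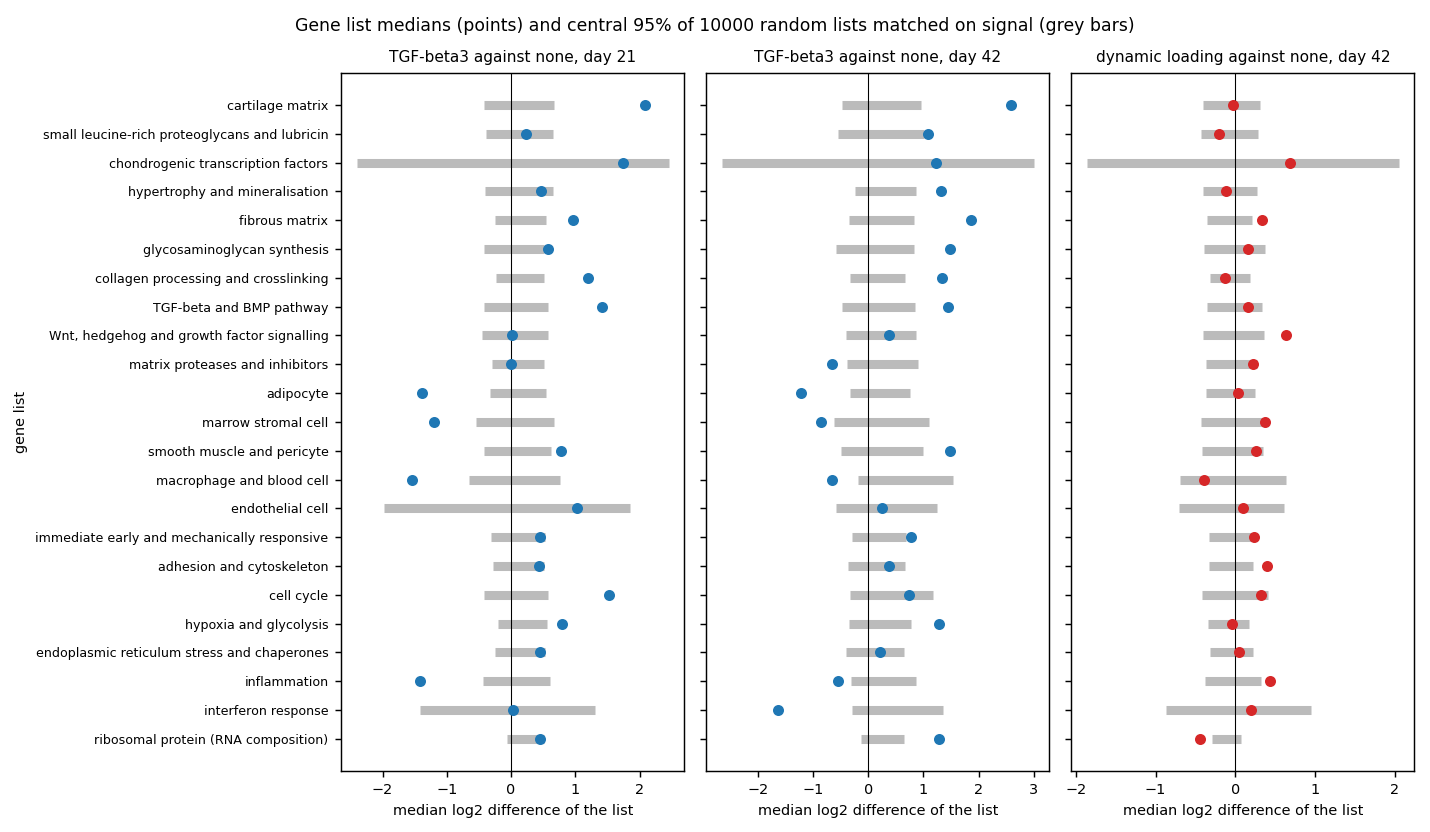
Median log2 difference (x axis) of the 23 gene lists (y axis) for TGF-beta3 at day 21, TGF-beta3 at day 42 and loading at day 42, with grey bars for the central 95% of 10000 random lists matched on signal. The cartilage matrix median stands at 2.08 and 2.58 for TGF-beta3 and at -0.03 for loading.

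Compression from day 21 to day 42 went with smaller differences than TGF-beta3. Type X collagen (COL10A1) was 6.99-fold higher in the loaded construct, with a signal of 748 against 107. The main cartilage genes differed by less than 2-fold: log2 0.74 for ACAN, -0.18 for COL2A1, -0.50 for COMP and -0.25 for HAPLN1. On this array pair the spikes differed by log2 -0.40 and probe sets over a signal of 1000 by a median of -0.13. The small negative values are thus not read as an effect of loading. The other 3 COL2A1 probe sets were 0.64 to 1.64 higher. The cartilage matrix list had 2 members at least 2-fold higher (COL9A1 and COL27A1, at 2.25-fold and 3.49-fold) and 1 lower (MATN1) of 12, with a median log2 difference of -0.03 that lay at percentile 59.6 of random lists. Lubricin (PRG4) was at least 5.58-fold lower and under the floor when loaded, although its other probe sets differed by log2 -1.38 to 0.15.

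Several inflammatory and early response genes were higher on the loaded array. Interleukin 6 (IL6) was 5.76-fold higher, the nitric oxide synthase NOS2 at least 6.46-fold, the antimicrobial peptides DEFB4A 9.36-fold and EBD 6.82-fold, and the inflammation list had 4 of 18 members higher and 1 lower (median log2 0.43, percentile 99.3). The stress-induced phosphatase DUSP1 was 6.33-fold higher and the AP-1 subunit FOSL1 3.78-fold, but EGR1 was 2.61-fold lower, and the immediate early list lay inside the central 95% of random lists (percentile 97.4). The chemokine CXCL12 was at least 6.84-fold higher, and the matrix proteases MMP3 and PLAU were 3.78-fold and 3.23-fold higher, though the other MMP3 probe sets differed by log2 -0.01 and by at least 0.20. The extracellular matrix protein ECM1 had the largest difference, 17.6-fold higher, and the mitotic protein CENPF was 8.60-fold higher with log2 3.10 on 1 probe set and 0.82 on another.

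Among matrix and adhesion genes, the fibrous matrix list was higher with loading (median log2 0.33, percentile 99.6), with COL6A2 4.50-fold and TNC 2.30-fold higher and ELN 2.85-fold lower, and COL1A1 at log2 0.88. A second probe set went the other way for TNC (log2 -0.44, under the floor when loaded) and for ELN (0.38). The adhesion and cytoskeleton list had a median of 0.39 (percentile 99.9), with the focal adhesion proteins VCL and ZYX 2.49-fold and 2.36-fold higher and the integrin ITGA3 at least 2.36-fold lower, though a second ZYX probe set stood at log2 -0.34. Wnt and growth factor genes had a median of 0.63 (percentile 99.9), with SFRP4 at least 4.18-fold and IGFBP4 3.19-fold higher. BMP2 and its inhibitor BAMBI were 2.57-fold and 3.65-fold higher. Ribosomal protein genes were lower (median -0.45, percentile 0.00), on an array pair whose spikes differed by -0.40. The other 18 lists lay inside the central 95% of random lists, among them hypertrophy (median -0.11), glycosaminoglycan synthesis (0.16), collagen processing (-0.14), proteases (0.21), adipocyte (0.03), stromal (0.37), smooth muscle (0.26), macrophage (-0.39), cell cycle (0.33), hypoxia (-0.04) and chaperone genes (0.04). Against day 21 with TGF-beta3, the same unloaded array had the fibrous matrix and adhesion lists lower (medians -0.34 and -0.45) and the ribosomal list higher. For these lists an effect of loading cannot be told apart from an unloaded array that stands apart.

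The unloaded day 42 array serves both this comparison and that of days 21 and 42, and of 797 genes at least 2-fold lower at day 42 than at day 21 with TGF-beta3, 277 were at least 2-fold higher with loading and 7 lower. By size, 1787 of 17448 probe sets were at least 2-fold higher and 1430 lower with loading, mostly on probe sets under a signal of 200, and of the 1343 probe sets over a signal of 1000 3.95% differed 2-fold. The 10 genes with the largest lower values, such as FKBPL, GNAT2, RHOG and FMR1, had signals on the loaded array between 15.2 and 66.9, close to the floor. A second probe set of the same gene was also at least 2-fold different the same way in 20.1% of 333 genes, against 53.6% of 506 genes for TGF-beta3 at day 21, and the loading count was 1043 with the floor at the 60th percentile. Genes at least 2-fold higher with TGF-beta3 at day 21, from arrays not used in the loading comparison, had a median loading difference of log2 0.00 over 972 genes, inside the central 95% of random lists, and the 876 genes lower with it had 0.06 (percentile 98.7). At the 3-fold threshold the higher genes lay outside that range (median 0.10, percentile 98.9) and the lower genes inside it (97.0), and with the median of all probe sets of a gene the higher genes also lay outside it (median 0.02, percentile 98.7).

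With TGF-beta3, cell cycle genes were lower and some matrix genes higher on the later day. Of 22 cell cycle genes 12 were at least 2-fold lower at day 42 than at day 21 and none higher (median log2 -1.28), with RRM2 14.7-fold lower. COL10A1 was under the floor at day 21 and at least 7.07-fold higher. The protease inhibitor SERPINA1 was 14.2-fold higher, the Wnt-binding SFRP5 11.7-fold and angiotensinogen (AGT) 10.7-fold. The proteoglycan versican (VCAN) was 16.1-fold lower, with its other probe sets at log2 -1.70 and, under the floor at day 42, -1.85, and the basement membrane protein NID1 11.6-fold lower. TNC was 3.81-fold and MMP13 at least 4.04-fold lower, and ACAN, COL2A1 and HAPLN1 stood at log2 -0.05, 0.99 and 0.98. Other probe sets differed from these, at -1.42 and -1.05 for ACAN, between -0.31 and 0.29 for COL2A1 and at least 0.44 higher for TNC. In all, 3059 of 16859 probe sets were at least 2-fold higher and 2381 lower, a split of 2012 and 3441 under median centring. The adipocyte list was higher (8 of 15, median 1.08), as were the cartilage matrix (0.78), hypertrophy (0.84), hypoxia (0.74) and ribosomal lists (1.03), on an array pair whose spikes differed by 1.23, and the fibrous (-0.34), smooth muscle (-0.45) and adhesion lists (-0.45) were lower.

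Without TGF-beta3, cartilage and fat cell genes were higher at day 21 than at day 3. COL2A1 was 49.4-fold higher, but on 1 of its 4 probe sets, the other 3 being at or under the floor. COMP was at least 15.9-fold higher, ACAN 2.23-fold and PRG4 3.77-fold (its other probe sets between log2 -0.09 and 1.93), and 4 of 9 cartilage matrix genes were at least 2-fold higher. Of 16 adipocyte genes 10 were higher and 1 lower (median 1.39), with CD36 18.3-fold higher, and the lipid genes ABHD5, GPAM and PDK4 were 30.0-fold, 20.8-fold and 27.3-fold higher. MMP13 was 20.6-fold lower, COL1A1 2.64-fold lower and the hypoxia-induced BNIP3 7.01-fold lower, and the fibrous matrix list had a median of -1.02 with 8 of 16 lower. The inflammation (-0.62), hypertrophy (-0.44), hypoxia (-0.41), Wnt and growth factor (-0.41), stromal (-0.39), protease (-0.35) and TGF-beta and BMP lists (-0.29) were lower too, as were ribosomal protein genes (-0.40), on an array pair whose spikes differed by -0.45. In all 1081 of 15054 probe sets were at least 2-fold higher and 783 lower.

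Between days 21 and 42 without TGF-beta3 few bright probe sets differed, 1.19% of the 1347 over a signal of 1000. Of 14737 probe sets 485 were at least 2-fold higher and 1485 lower, a split of 774 and 902 under quantile normalization and 1368 and 850 under median centring. From the earlier to the later array the 3 prime to 5 prime ratios of control probe sets went from 1.72 to 2.27 for GAPDH, 5.11 to 6.34 for cyclophilin and 5.14 to 9.10 for eIF4E. Interferon-response genes, which cells switch on against viruses, stood out: 6 of 9 were at least 2-fold higher at day 42, with a median log2 difference of 1.77. ISG15 was at least 20.9-fold higher, MX1 at least 8.03-fold and IFI6 4.95-fold. The day 42 array of this comparison is also the array against which ISG15 and MX1 were lower with TGF-beta3. The same list had been lower at day 21 than at day 3 (6 of 9 lower, median -1.36), with ISG15 at least 9.38-fold lower. COL1A1 was 3.15-fold lower at day 42 and MMP13 2.28-fold higher, while ACAN, COL2A1, COMP and PRG4 differed by log2 -0.47, 0.23, 0.71 and 0.20. The fibrous matrix (-0.50), stromal (-0.40), glycosaminoglycan synthesis (-0.35), adhesion (-0.27), small leucine-rich proteoglycan (-0.18) and collagen processing (-0.09) lists had medians under those of random lists, and under median centring of the arrays the last 5 of these went above 0, to 0.02, 0.02, 0.10, 0.19 and 0.27 in the same order.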

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

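The tests on ribosomal protein genes, on the array correlations and on blood cell markers were chosen after those results had been seen, and the test across probe sets before. The hybridisation spikes, which no comparison uses, were higher by log2 1.39 on the unloaded day 42 array with TGF-beta3 than on the day 42 array without it, and by 0.99 on the loaded one. From day 21 to day 42, CHPF was higher by log2 2.08 with TGF-beta3 but differed by -1.01 without it. DEFB4A differed by -1.82 with it and 1.29 without. CNN1 differed by -1.67 with it and was at least 1.12 higher without, from under the floor, and MMP13 differed by -2.01 with it, a bound since it went under the floor, and by 1.19 without.

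The ribosomal protein genes were higher with TGF-beta3 at day 42 by a median log2 of 1.28. Their shift lay -0.11 from that of the spikes, so a difference between the arrays in scale or signal distribution that the spikes share may account for it. More ribosomal protein transcript cannot be told apart from this, since the excess over other genes depends on how signal is matched. It was log2 1.06 over random lists from the same signal deciles, which are wide at the bright end. Over the 10 genes nearest to each it was 0.15 (SD over genes 0.44), and 0.14 to 0.18 over 4 ways of choosing the nearest genes. Of the 27 ribosomal protein genes 24 lay above their nearest genes, and those 89 nearest genes as a set shifted by a median log2 of 0.62. With genes called by limma left out of the nearest genes, the excess was 0.21 (SD over genes 0.47). The authors' scaling holds the trimmed mean fixed, and why the spikes were brighter on both day 42 arrays with TGF-beta3 was not tested.

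Genes that differed between days 21 and 42 with TGF-beta3 tended to go the other way on the loaded array. Of 797 genes at least 2-fold lower at day 42, 277 were at least 2-fold higher with loading and 7 lower, and of 1472 higher at day 42, 22 were higher with loading and 385 lower. Both comparisons use the unloaded day 42 array, so its errors enter with opposite signs. Across 2206 genes with a second probe set, the time difference on 1 probe set correlated at -0.14 (bootstrap interval -0.18 to -0.11) with the loading difference on the other, against -0.56 on the same probe set, so errors of single probe sets are argued against as the whole explanation but may make up much of it. That the unloaded sample or array stands apart as a whole cannot be told apart from an effect of loading, since the loaded array correlated more closely than the unloaded one with 4 of the 4 other arrays and each condition has 1 array.

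Macrophage and blood cell markers were lower with TGF-beta3. Only 1 marker (CD14, mean log2 difference -1.07) was above the floor on all 4 arrays, too few to ask whether the markers fell in 1 ratio, so fewer cells of blood lineage cannot be told apart from lower expression within cells.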

How the results depend on the processing

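No paired analysis was possible by replicate number because each condition has 1 array, while the TGF-beta3 test matched the arrays by day. The floor at a signal of 100 and the exchange of the loaded for the unloaded array were chosen after seeing the data. Counts moved with the floor, the size rule and the unit counted, which by construction change how many can pass. In the order TGF-beta3 at day 21, TGF-beta3 at day 42, loading, days 21 to 42 with TGF-beta3, days 21 to 42 without it and days 3 to 21, the counts were 4480, 6861, 3217, 5440, 1970 and 1864. They were 2508, 3493, 1043, 2366, 658 and 817 with the floor at the 60th percentile, 7869, 10413, 7136, 9273, 4897 and 4849 at 1.5-fold, 2033, 3495, 1007, 2153, 533 and 555 at 3-fold, 1960, 3113, 1219, 2298, 623 and 794 for genes, and 1775, 2376, 533, 1483, 298 and 531 with the floor at a signal of 100. With the floor at the 25th percentile the last 4 comparisons had 5992, 8442, 3474 and 3220. Of 84 alternatives for counts and list tests, 40 stayed within 1.5 times or the random spread.

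Where the scaling or floor shifted the split, higher and lower counts for TGF-beta3 at day 42 were 2472 and 4820 under median centring, 1749 and 1744 at the 60th percentile and 1159 and 1217 at a signal of 100. For days 21 to 42 they were 2012 and 3441 with TGF-beta3 under median centring, and without TGF-beta3 774 and 902 under quantile normalization, 1368 and 850 under median centring, 256 and 367 for genes and 107 and 191 at a signal of 100. The limma count of 1954 was 1030 without a variance trend and 570 without the day term, which by construction leaves the day difference in the residual, and 340, 370, 2137 and 3773 with 1 array left out and no day term, where an arm has 1 array and the spread comes from the other arm and the pooled prior. Median centring gave 488 that rose and 1008 that fell. It was 2488 with the loaded array in place of the unloaded one.

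For loading, the genes higher with TGF-beta3 at day 21 had a median of -0.068 under median centring, -0.051 with the floor at the 60th percentile, -0.058 at a signal of 100 and 0.10 at 3-fold, and the genes lower with it 0.015 under median centring. Of 552 alternatives for list medians 149 moved and 6 changed sign, and of 748 for named genes 132 moved. For 7 genes named with a limma p-value, 92 of 100 alternatives kept the call or the lack of one. These were CD36, CHAD, COMP, HAPLN1, MMP13, PITX1 and PRG4, so the 92 does not describe the 1954 calls. Of those, 1006 were shared without the variance trend and 570 without the day term. Under median centring, for days 21 to 42 without TGF-beta3, small leucine-rich proteoglycans went to 0.19, glycosaminoglycan synthesis to 0.023, collagen processing to 0.27, stromal genes to 0.016 and adhesion genes to 0.10, and under quantile normalization the ribosomal list of days 3 to 21 went to 0.022. With the median of all probe sets of a gene, the inflammation list for TGF-beta3 at day 42 went from -0.55 to 0.00, which was not counted as a change of sign, a reading settled after the value was seen. Among the tested genes, HAPLN1 did not pass without the variance trend or without the day term, and PITX1 rose with the loaded array in place of the unloaded one (adjusted p = 0.0221). In the fits with 1 array and the day term left out, MMP13 turned to a log2 difference of 0.18 without the day 42 array with TGF-beta3 and passed at -1.83 without the day 21 one (adjusted p = 0.0358), PITX1 passed without the day 42 array with TGF-beta3 (0.0328), and HAPLN1 did not pass without the day 21 (0.507) or day 42 array (0.643) without TGF-beta3. These p-values compare 1 array in an arm with 2 in the other. The cause was not tested. Signal close to the floor limits the dim probe sets, and a dim gene named on 1 probe set is the least certain.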

Other observations

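Metallothioneins, small proteins that bind zinc and respond to metals and stress, were not in any list and were noticed after their values were seen. MT1A was higher by log2 3.09 with TGF-beta3 at day 21 and 1.05 at day 42, and 5.58-fold higher on the loaded than on the unloaded day 42 array. MT2A differed by log2 3.52 and 1.45 with TGF-beta3 and was 6.06-fold higher with loading. Without TGF-beta3 their signals at day 42 were 162 and 255, and on the loaded array 1869.8 and 4202.

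The proteoglycan versican (VCAN), typical of loose connective tissue, was lower with TGF-beta3 where aggrecan was higher. Its signal was 3262 at day 3 and 1785 at day 42 without TGF-beta3, and with it 291 at day 21 and, at day 42, 58.0 when loaded, log2 1.69 above the unloaded array. It was 7.75-fold lower with TGF-beta3 at day 21 and 98.9-fold lower at day 42, where its other probe sets were at log2 -4.25 and, under the floor, -5.01. The antimicrobial peptide gene DEFB4A was 74.4-fold lower with TGF-beta3 at day 42 (at least log2 1.71 lower on a second probe set) and 9.36-fold higher on the loaded than on the unloaded array, where its signal of 287 stayed under the 2283 measured without TGF-beta3.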
